A study of Mus musculus with 1483 samples.

How the data were processed

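Single neurons were isolated from the tissue the labels call VISp of C57Bl/6J mice that carried an enhancer virus expressing SYFP2, sorted for fluorescence, and sequenced from polyadenylated RNA with the SMART-Seq v4 chemistry. The deposited table holds 1483 cells and 45768 genes, of which 9567 were at 0 in every cell. Its values are counts per 1000000 reads (CPM) that the authors computed per cell, so that each cell sums to that number. The submitters' processing notes name STAR and mm10 without a version or a role. The counting program, the annotation, the cell filters and the age of the mice are not given in the sources used here. Within each cell, 100% of the values above 0 were whole multiples of 1 read within 0.01 read, so reads per cell were recovered from the CPM. All genes and all cells were used.

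Reads per cell ranged from 833 to 1018507, with a median of 586338, and the next lowest cell had 28853. The shallowest cell, with 375 genes, came from an eHGT_019h mouse and was the 1 cell with fewer than 4000 genes. In it 1 read is 1200.5 CPM. Another limit is that 16 cells had fewer than 100000 reads. The reads carry no molecular identifiers, so reads are not independent molecules. Of the 33 mice, 24 had library names with prefix letter G and 9 with J, over 32 prefixes, some of which mice of different enhancers share. One mouse of eHGT_128h has 53 cells, above the 48 that the design text gives as the maximum. No doublet caller was run.

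Cells were clustered from log2(CPM + 1) of the 3000 most variable genes by 30 principal components, a shared-neighbour graph over 15 nearest neighbours and Leiden clustering at resolution 1 with a fixed seed (igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, figures by matplotlib 3.10.9). A cluster was named for the marker list with the highest mean log2 difference when at least 3 of its markers were at 10 CPM or more in at least 50% of the cluster's cells and no other list had more markers among its 10 leading genes, which had to reach 10 CPM in at least 25% of the cells. The criterion for leading genes, the fold against cells of clusters best matched by other lists, was chosen after the clusters were seen. With the fold against all other cells, clusters of 179 Sst-like and 54 Lamp5-like cells were left unnamed, and with the log2 difference a cluster of 38 L2/3 IT-like cells was. The 179 cells came mostly from eHGT_064h (54), eHGT_023h (32), eHGT_079h (27), eHGT_017h (25) and eHGT_128h (18), and the 54 from eHGT_019h (25), eHGT_017h (14) and hDLXI56i (12). The 38 cells came from eHGT_078h (27), eHGT_023h (9), eHGT_017h (1) and eHGT_058h (1). The cluster of 83 glutamatergic cells that stayed unnamed came from eHGT_078h (46), eHGT_058h (27), eHGT_023h (9) and eHGT_082h (1). Cells were also read without clusters, from Gad1, Gad2 and Slc17a7 at a threshold of 10 CPM.

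The mouse was the replicate, in 11 enhancer groups. The tests, gene lists and most alternatives were fixed before the data were examined. Shares per mouse were compared by 2-sided exact permutation tests over 5456 assignments of mice (40920 for eHGT_064h and 528 for eHGT_082h), with Benjamini-Hochberg adjustment over all pairs of enhancer and class, and by omnibus permutation tests with 100000 resamples. edgeR and DESeq2, with a size factor alternative, were planned for a table of raw counts and were not run, on the reads recovered from the CPM either, which entered voom alone. The plan gave limma to a table of CPM, so limma became the main test. This was limma 3.58.1 (trend and robust, statmod 1.5.0) on log2 of the mean CPM per mouse + 1, for genes with at least 1 CPM in at least 2 mice, called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. For each enhancer its mean was set against the unweighted mean of the 10 other enhancers in 1 fit of all 33 mice. Within a class, mice with at least 5 cells, enhancers with at least 2 such mice and classes with at least 3 such enhancers entered an omnibus limma test without the fold limit, which left the Pvalb and Sst classes. The prefix letters were compared in an additive limma model with enhancer. The fit was tested on simulated data, with changes of each of 2 sizes added to 100 genes in the mice of eHGT_128h. It called 97 of them at a log2 size of 1.5 and 99 at 3, with 5 unchanged genes. The omnibus test called 90 and 98, with 13 unchanged genes. These counts hold for the simulated values, and how far they carry over to the real mice, or to genes of lower mean, was not tested.

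Genes named per enhancer were the 4 largest rises and the 2 largest falls among called genes with a mean of at least 20 CPM on the higher side and every mouse beyond the median of the other mice. Xist, Tsix, Y-linked genes, genes without an official symbol, pseudogenes, and mitochondrial and ribosomal protein genes were left out. Within a class these were the 10 genes of smallest adjusted p, 1 of which is not reported here. Other genes are members of fixed lists, and the members given with values were picked after their values were seen. The lists were markers of neurons, GABAergic, glutamatergic, MGE-derived, CGE-derived, Pvalb, chandelier, Sst, Vip, Sncg, Lamp5, L2/3 IT, L4 and L5 IT, L5 ET, L5/6 NP, L6 IT, L6 CT and L6b cells, astrocytes, oligodendrocytes and their precursors (OPC), microglia, endothelium, pericytes and VLMC, and the transmitter, DLX, perineuronal net, fast-spiking channel, neuropeptide, calcium-binding, immediate early, interferon and housekeeping genes. Coordinates come from the RefSeq annotation of GRCm38.p6. Fam19a1 was matched to it through its synonyms.

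Alternatives were pseudocounts of 0.1 and 10, no filter on low values, cells with at least 4000 genes, the prefix letter as a covariate or letter G mice only, Leiden resolutions of 0.5 and 2, 1500 variable genes, transmitter thresholds of 1 and 100 CPM, thinning to 100000 reads, Pearson correlation, the 3000 most variable genes, pairs sharing no prefix, at least 10 cells per class, and leaving out each mouse. Chosen after the data were seen were limma voom on recovered reads, both other ways of naming clusters, and fits without the 3 enhancers of fewest genes per cell (hDLXI56i, eHGT_017h and eHGT_019h).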

Results

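The data were full-length single-cell transcriptomes of neurons from the mouse tissue that the labels call VISp, a name used for primary visual cortex. Each mouse, of strain C57Bl/6J, carried an adeno-associated virus in which 1 candidate enhancer drove the yellow fluorescent protein SYFP2, and fluorescent cells were sorted and sequenced 1 by 1. There were 11 enhancers, 33 mice and 1483 cells. Of the enhancers, 9 had 3 mice each, eHGT_064h had 4 and eHGT_082h had 2. A mouse gave between 32 and 53 cells, and the mouse was the replicate throughout. Total reads per mouse, recovered from values in counts per 1000000 reads (CPM), ranged from 17123364 in an eHGT_017h mouse to 35856031 in an eHGT_128h mouse. The median cell held 586338 reads and 9709 detected genes. Median genes per cell ranged from 8788 in hDLXI56i to 10249 in eHGT_082h. In the median cell, 1 read was 1.71 CPM.

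Nearly all cells read as neurons, and most as GABAergic neurons. The 19 clusters held 1202 GABAergic and 281 glutamatergic cells, and 0 clusters were of another kind. Naming whole clusters does not exclude single cells of another kind. By the marker lists, 619 cells were Pvalb-like, 332 Sst-like, 197 Lamp5-like and 54 Vip-like. Of the glutamatergic cells, 106 were L4 and L5 IT-like (intratelencephalic), 54 L5 ET-like (extratelencephalic), 38 L2/3 IT-like, and 83 formed 1 cluster that no list named, led by Fst, Rmst, Tnfaip6 and Tnnc1. One Lamp5-like cluster of 54 cells was led by both Ndnf and Sncg. At the finer clustering a cluster of 21 cells was named Sncg-like.

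Which classes an enhancer labels was the question the design asks of every group. The class mix differed between the 11 enhancers in permutation tests, with p = 1e-05, the smallest the resamples can give, for the GABAergic, Pvalb-like, Sst-like, Lamp5-like and L5 ET-like shares. The permutation p was 3e-05 for L4 and L5 IT-like, 0.0002 for the unnamed cluster, 0.003 for Vip-like and 0.007 for L2/3 IT-like cells. Mice of 1 enhancer resembled one another more than mice of different enhancers. The overlap of class shares averaged 0.806 over 34 pairs of mice with the same enhancer and 0.328 over 494 pairs with different ones. Spearman correlations of expression profiles, computed across genes, averaged 0.960 and 0.921 over the same pairs. In 1-sided permutation tests each difference had p = 1e-05, the smallest possible. Among pairs that shared no library prefix the differences were 0.502 for class overlap and 0.0394 for the correlation. Within-enhancer overlap was 95.3% in eHGT_140h, 94.8% in eHGT_128h and 94.6% in eHGT_064h. It was 57.7% in eHGT_023h, whose mice overlapped more, by 63.4%, with eHGT_079h mice, and 83.5% in eHGT_082h, against 88.9% with eHGT_128h mice.

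**Figure D1:**
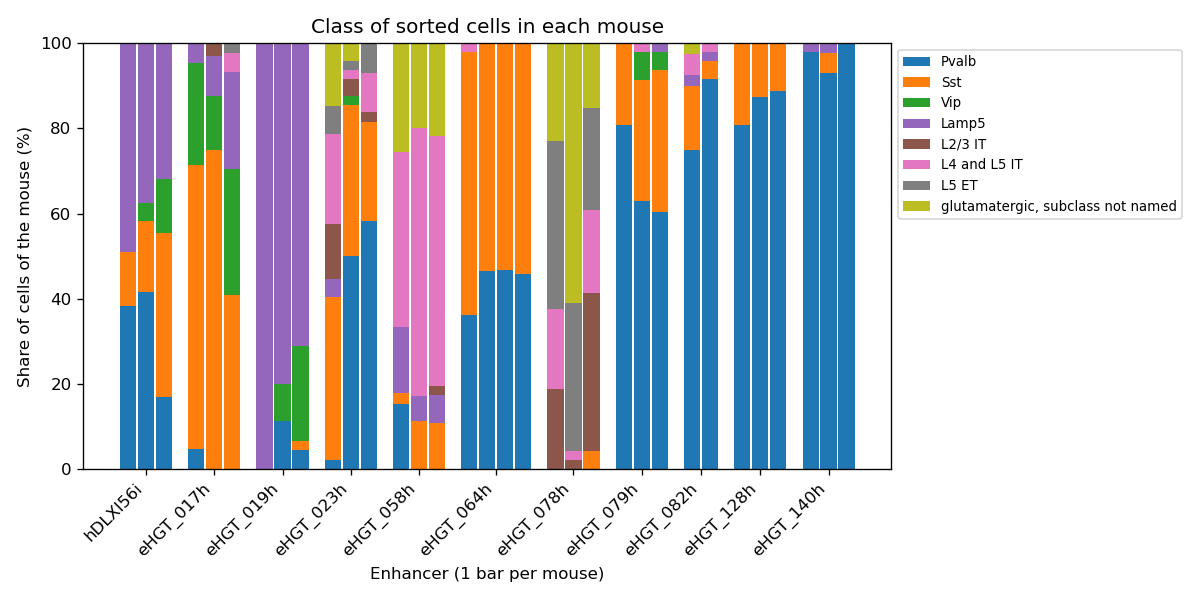
Share of each mouse's cells (percent, y axis) in 8 classes, with 1 stacked bar per mouse and the 33 mice grouped by enhancer. Bars of eHGT_140h, eHGT_128h and eHGT_082h are mostly Pvalb-like, those of eHGT_019h mostly Lamp5-like, and those of eHGT_058h and eHGT_078h mostly glutamatergic.

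Transmitter genes read directly in each cell gave a like picture without clustering. With a threshold of 10 CPM, 1125 cells had Gad1 or Gad2, the GABA-synthesising enzymes, without Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons. The reverse held in 278 cells, both held in 79, and neither in 1. In eHGT_078h, 97.1% ± 2.51 of the cells were glutamatergic (SD, n = 3, adjusted exact permutation p = 0.00269) and 1.45% ± 2.51 GABAergic. In eHGT_058h these shares were 76.7% ± 8.73 and 21.9% ± 9.95 (n = 3), with an adjusted exact permutation p of 0.05 for each, which did not pass. Cells with both sets of genes made up 22.4% ± 12.8 in eHGT_019h (14.6%, 37.1% and 15.6% in its 3 mice) against 3.88% in the other mice (adjusted exact permutation p = 0.00269). That call ended at a threshold of 100 CPM.

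For each enhancer, expression per mouse was then compared with the unweighted mean of the other 10 enhancers in 1 limma fit of 18932 genes. Values below are mean CPM ± SD over the enhancer's mice against the unweighted mean of the other 10 enhancers' mean CPM. The log2 differences are taken on mean log2 values, so low and skewed genes can show a log2 difference unlike the ratio of the printed means. A pseudocount of 10 in place of 1 lowered every count of called genes by over 1.5 times, to between 28 in eHGT_023h and 992 in eHGT_078h. Where limma voom on recovered reads, an alternative chosen after the data were seen, moved the share of called genes that were higher by over 10 percentage points, or the total by over 1.5 times, its counts stand beside the main ones. Shares of classes were compared by exact permutation over mice, adjusted over all pairs of enhancer and class. Coordinates are from the GRCm38.p6 annotation, the build the submitters' notes name as mm10.

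eHGT_078h labelled glutamatergic neurons of several layers and almost no GABAergic ones. GABAergic clusters held 1.45% ± 2.51 of its cells against 88.6% in the other mice (n = 3, adjusted exact permutation p = 0.00363). L5 ET-like cells made up 32.8% ± 8.03 (adjusted exact p = 0.00363), L2/3 IT-like cells 19.3% ± 17.4 (adjusted exact p = 0.0156) and the unnamed glutamatergic cluster 33.0% ± 24.4 (adjusted exact p = 0.0163). The largest rises were Fam19a1 (chromosome 6, 96113154 to 96657204), a secreted chemokine-like protein, with 676 ± 167 CPM against 62.6 CPM, log2 difference 6.34, SE 0.89, adjusted p = 4.29e-06, Slc17a7 (chromosome 7, 45163921 to 45176139) at 978 ± 286 CPM against 118 CPM, log2 6.03, the neurite growth factor Nrn1 (chromosome 13, 36725622 to 36734477) at 556 ± 214 CPM against 74.8 CPM, log2 5.86, and Fezf2 (chromosome 14, 12338992 to 12346803), a transcription factor of corticofugal neurons, at 146 ± 41 CPM against 5.76 CPM, log2 5.77. Gad1 (chromosome 2, 70561303 to 70602014) was the largest fall, at 26.3 ± 43.7 CPM against 2682 CPM, log2 difference -8.58, SE 0.63, adjusted p = 3.69e-10, followed by the neuregulin receptor Erbb4 (chromosome 1, 68031884 to 69108576) at 0.649 ± 0.725 CPM against 708 CPM, log2 -8.36. All glutamatergic markers rose, 7 of 7 higher (7 adjusted over the list alone), and all GABAergic markers fell, 6 of 6 lower (6 adjusted over the list alone). The DLX family, here interneuron transcription factors and the non-coding RNA Dlx6os1, fell too, 5 of 5 lower (5 adjusted over the list alone), Dlx2 to 0.0893 ± 0.155 CPM. Of the L5 ET markers 3 of 6 higher (3 adjusted over the list alone), including Crym at 131 ± 27 CPM against 6.93 CPM, log2 5.58 and Pou3f1 at 47.4 ± 18.9 CPM against 1.95 CPM, log2 4.54. L6 CT (corticothalamic) markers were 3 higher and 0 lower of 4 (3 and 1 adjusted over the list alone), L2/3 IT markers 4 of 8 higher (4 adjusted over the list alone) and L4 and L5 IT markers 4 of 8 higher (4 adjusted over the list alone). Crym stands on both the L5 ET and the L6 CT list, so its call counts in both. Immediate early genes, which report recent activity, were 7 of 12 higher (8 adjusted over the list alone), and fast-spiking channel genes 9 of 12 lower (9 adjusted over the list alone), Kcnc1 at 36 ± 8.91 CPM against 399.8 CPM, log2 -3.18. Neuropeptides were 2 higher and 7 lower of 16 (2 and 9 adjusted over the list alone), with Npy at 35.3 ± 59.0 CPM and Cck at 1717 ± 438 CPM against 379 CPM, log2 2.50. In all, 1702 genes were higher and 1015 lower. The L2/3 IT-like share did not pass with clusters named by log2 difference, with letter G mice only, or without MouseID-453328 (18.7 points above the other mice) or MouseID-498749 (9.64 points). The unnamed cluster's share did not pass with letter G mice only or without MouseID-453328 (35.1 points) or MouseID-454782 (16.1 points).

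eHGT_058h also labelled mainly glutamatergic neurons, most of them L4 and L5 IT-like. Those made up 54.2% ± 11.6 of its cells against 2.97% in the other mice (n = 3, adjusted exact permutation p = 0.00363). GABAergic clusters held 22.6% ± 9.28 against 86.5% (adjusted exact permutation p = 0.0478). The unnamed glutamatergic cluster held 22.5% ± 2.89 against 4.02%, which did not pass (adjusted exact permutation p = 0.227). The top rises were Dkkl1 (chromosome 7, 45207525 to 45212165), a secreted Dickkopf-like protein, at 229 ± 24.2 CPM against 17 CPM, log2 difference 6.04, SE 0.52, adjusted p = 1.68e-09, Slc17a7 at 844 ± 88.9 CPM against 132 CPM, log2 5.85, Nrn1 at 499 ± 103 CPM against 80.4 CPM, log2 5.76 and Fam19a1 at 388 ± 133 CPM against 91.4 CPM, log2 5.42. The largest falls were Pthlh (chromosome 6, 147252109 to 147264013), parathyroid hormone-like hormone, at 1.66 ± 1.35 CPM against 52 CPM, log2 difference -3.74, SE 0.63, adjusted p = 6.25e-05, and the lipoprotein lipase gene Lpl (chromosome 8, 68880555 to 68906932) at 5.66 ± 8.64 CPM against 50.6 CPM, log2 -3.28. Markers of L4 and L5 IT cells were 7 of 8 higher (7 adjusted over the list alone), among them Rorb, a nuclear receptor of layer 4, at 226 ± 67.6 CPM against 15.7 CPM, log2 4.92 and Endou at 50.6 ± 13.3 CPM against 1.48 CPM, log2 5.15. Glutamatergic markers were 7 of 7 higher (7 adjusted over the list alone) and GABAergic markers 3 of 6 lower (3 adjusted over the list alone), Slc32a1, the vesicular GABA transporter, at 10.2 ± 5.39 CPM against 52.9 CPM, log2 -1.97. Immediate early genes rose, 10 of 12 higher (10 adjusted over the list alone): Arc was at 509 ± 169 CPM against 33 CPM, log2 5.42, Egr1 at 1299.9 ± 359.8 CPM against 161 CPM, log2 3.85 and Nr4a1 at 287 ± 92.2 CPM against 34.1 CPM, log2 3.99. The DLX family was 5 of 5 lower (5 adjusted over the list alone), Dlx5 at 13.8 ± 4.25 CPM against 53.5 CPM, log2 -1.51, and the calls of Dlx1, Dlx2 and Dlx6os1 ended with voom. Fast-spiking channel genes were 6 of 12 lower (6 adjusted over the list alone), Scn1a at 133 ± 25.9 CPM against 369.6 CPM, log2 -1.38. Calls numbered 1772 higher and 597 lower. Voom ended the call of Pthlh, and the call of the GABAergic share ended under 3 alternatives and without 1 of 29 mice, its own 3 among them, where the difference stayed between -69.2 and -61.1 points. Other cluster names left that share unchanged, and there its call ended through the adjustment alone.

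eHGT_023h labelled a mix that varied between its mice. Its cells were 71.2% ± 23.2 GABAergic (n = 3), with Pvalb-like shares of 2.13%, 50.0% and 58.1% in the 3 mice and Sst-like cells at 32.3% ± 7.98. No class share passed its test. In expression, 111 genes were higher and 12 lower (425 and 10 with voom). Fam19a1 was at 171 ± 101 CPM against 113 CPM, log2 difference 4.02, SE 0.89, adjusted p = 0.0253, Itpka (chromosome 2, 119742337 to 119751253), an inositol trisphosphate kinase of dendritic spines, at 113 ± 78.1 CPM against 68.7 CPM, log2 3.28, and the transcription factor Neurod6 (chromosome 6, 55677818 to 55681263) at 68.4 ± 55.5 CPM against 42.2 CPM, log2 3.27. Slc17a7 was at 203 ± 143 CPM against 196 CPM, log2 3.34, so its rise lay in the log2 means, since several other enhancers were near 0. The falls were Hap1 (chromosome 11, 100347327 to 100356982), a huntingtin-associated protein, at 5.75 ± 1.36 CPM against 20.5 CPM, log2 difference -1.50, SE 0.26, adjusted p = 0.00163, and Dpysl5 (chromosome 5, 30711564 to 30799369), a collapsin response mediator, at 7.41 ± 1.73 CPM against 21.1 CPM, log2 -1.27. Glutamatergic markers were 6 of 7 higher (7 adjusted over the list alone), L5 ET markers 2 of 6 higher (3 adjusted over the list alone) and L6 CT markers 1 of 4 higher (2 adjusted over the list alone). All 3 mice carried prefix letter J, and with that letter as a covariate 29 genes passed, the calls of all named genes but Itpka ending. Those of Fam19a1, Slc17a7 and Neurod6 also ended with a pseudocount of 0.1, those of Hap1 and Dpysl5 with 10, and those of Slc17a7, Neurod6 and Dpysl5 without the 3 enhancers of fewest genes per cell. Leaving out any 1 of the 3 mice ended the calls of Fam19a1 (log2 3.58 to 4.42) and Slc17a7 (2.80 to 3.79, also without the eHGT_128h MouseID-473546), MouseID-497548 or MouseID-498748 that of Neurod6 (2.64 to 3.32), and MouseID-497548 that of Dpysl5 (-1.10). Without MouseID-497548 the count was 36.

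eHGT_019h labelled Lamp5-like interneurons. These made up 83.7% ± 14.8 of its cells against 6.61% in the other mice (n = 3, adjusted exact permutation p = 0.00363), and Vip-like cells were at 10.3% ± 11.2. The largest rises were Cplx3 (chromosome 9, 57599992 to 57606281), a complexin of the vesicle release machinery, at 618 ± 164 CPM against 45.2 CPM, log2 difference 6.37, SE 0.84, adjusted p = 3.61e-06, Adarb2 (chromosome 13, 8202526 to 8768762), a marker of interneurons from the caudal ganglionic eminence (CGE), at 1108 ± 484 CPM against 104 CPM, log2 6.35, the secreted factor Ndnf (chromosome 6, 65671611 to 65712323) at 228 ± 122 CPM against 8.12 CPM, log2 6.20, and the peptide Vip (chromosome 10, 5639193 to 5647617) at 2194 ± 2191 CPM against 870.0 CPM, log2 6.18. The peptide Sst (chromosome 16, 23889573 to 23891342) fell, at 63.7 ± 109 CPM against 2316 CPM, log2 difference -6.01, SE 1.45, adjusted p = 0.00358, and the opioid precursor Pdyn (chromosome 2, 129686549 to 129699938) was listed at 0 in all 3 mice against 252 CPM. Lamp5 markers were 7 of 7 higher (7 adjusted over the list alone), with Lamp5 at 1497 ± 319.8 CPM against 241 CPM, log2 5.51, Id2 at 1237 ± 209 CPM against 201 CPM, log2 4.27 and Npy at 14683 ± 8839 CPM against 2790.2 CPM, log2 3.89. CGE markers were 3 of 4 higher (4 adjusted over the list alone), markers of the medial eminence (MGE) 2 of 4 lower (3 adjusted over the list alone) and Pvalb markers 5 of 7 lower (5 adjusted over the list alone). Satb1, an MGE regulator, was at 12.9 ± 4.59 CPM against 231 CPM, log2 -4.01. Fast-spiking channel genes were 1 higher and 6 lower of 12 (1 and 6 adjusted over the list alone) and perineuronal net genes 2 higher and 4 lower of 9 (2 and 4 adjusted over the list alone), Hapln1, a link protein of the net, rising to 424 ± 67.3 CPM against 44.6 CPM, log2 3.86 while Hapln4 was at 52 ± 7.30 CPM against 145 CPM, log2 -1.17. Neuropeptides were 3 higher and 4 lower of 16 (3 and 5 adjusted over the list alone), Pnoc at 489.6 ± 172 CPM against 65.9 CPM, log2 3.75. Interferon response genes were 2 of 10 lower (2 adjusted over the list alone), Ifit3 at 1.01 ± 0.974 CPM against 21.7 CPM, log2 -3.06. The counts were 1095 higher and 726 lower (1720 and 678 with voom). Voom ended the calls of Vip and Pdyn, and leaving out 1 of 2 mice ended those of Vip (log2 5.12 to 5.71, mice MouseID-400156 and MouseID-401668) and Sst (log2 -4.89 without MouseID-392043 or MouseID-400156).

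hDLXI56i labelled a mix of GABAergic classes. Lamp5-like cells were at 39.5% ± 8.68, Pvalb-like at 32.3% ± 13.4, Sst-like at 22.6% ± 13.8 and Vip-like at 5.64% (n = 3), and none of these shares passed its test. Cplx3 was at 295 ± 81.0 CPM against 77.5 CPM, log2 difference 5.19, SE 0.84, adjusted p = 2.70e-04, Adarb2 at 418 ± 214 CPM against 173 CPM, log2 4.81, the troponin gene Tnnt1 (chromosome 7, 4504569 to 4515975) at 105 ± 59.8 CPM against 18.7 CPM, log2 4.52 and the phosphodiesterase gene Pde11a (chromosome 2, 75985808 to 76339145) at 103 ± 25.7 CPM against 24.1 CPM, log2 4.47. Slc17a7 fell to 0.993 ± 0.738 CPM against 216 CPM, log2 difference -3.84, SE 0.78, adjusted p = 0.00261, and Nrn1 to 1.01 ± 0.932 CPM against 130.2 CPM, log2 -3.11. The DLX family was 4 of 5 higher (4 adjusted over the list alone), Dlx6os1 at 297 ± 98.0 CPM against 133 CPM, log2 2.10. Lamp5 markers were 7 of 7 higher (7 adjusted over the list alone), GABAergic markers 4 of 6 higher (4 adjusted over the list alone), CGE markers 3 of 4 higher (3 adjusted over the list alone) and glutamatergic markers 6 of 7 lower (7 adjusted over the list alone). Neuropeptides were 4 of 16 higher (4 adjusted over the list alone), with Npy at 14935 ± 7248 CPM against 2765 CPM, log2 3.93 and Pnoc at 262 ± 72.6 CPM against 88.7 CPM, log2 2.78. Calls were 443 higher and 145 lower (967 and 75 with voom), in all 929 without MouseID-400157 and 348 without MouseID-384912. Voom ended the calls of Slc17a7 and Nrn1, and that of Nrn1 also ended with a pseudocount of 0.1, without a filter, and without any 1 of the 3 mice (log2 -3.42 to -2.67).

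eHGT_017h labelled Sst-like and Vip-like interneurons. Sst-like cells made up 60.9% ± 17.8 against 18.9% in the other mice (n = 3, adjusted exact permutation p = 0.0163) and Vip-like cells 22% ± 8.67 against 2.02% (adjusted exact permutation p = 0.00907). Vip was at 5325 ± 3648 CPM against 557 CPM, log2 difference 8.38, SE 2.02, adjusted p = 0.00736, Tac2 (chromosome 10, 127724478 to 127731768), the neurokinin B precursor, at 456 ± 302 CPM against 59.9 CPM, log2 6.27, the stress hormone Crh (chromosome 3, 19693401 to 19695396) at 689.6 ± 413 CPM against 86.7 CPM, log2 5.76 and the serotonin-gated channel Htr3a (chromosome 9, 48899213 to 48911152) at 255 ± 133 CPM against 22.4 CPM, log2 5.67. Syt2 (chromosome 1, 134646534 to 134753149), a calcium sensor of fast release, fell to 0.546 ± 0.473 CPM against 62.8 CPM, log2 difference -4.31, SE 0.75, adjusted p = 3.97e-04, and the calcium buffer Pvalb (chromosome 15, 78191112 to 78206400) to 48.9 ± 67.8 CPM against 1199.6 CPM, log2 -3.95. Neuropeptides were 7 of 16 higher (8 adjusted over the list alone), with the enkephalin precursor Penk at 651 ± 289 CPM against 51.6 CPM, log2 5.65 and Pdyn at 1096 ± 376 CPM against 143 CPM, log2 5.25. Sst markers were 4 of 8 higher (4 adjusted over the list alone), Elfn1 at 91.7 ± 32 CPM against 15.4 CPM, log2 3.11 and Grin3a at 315 ± 99.6 CPM against 59.9 CPM, log2 2.98. Vip markers were 4 of 7 higher (5 adjusted over the list alone) and CGE markers 4 of 4 higher (4 adjusted over the list alone), with Nr2f2 at 71.3 ± 27.6 CPM against 13.8 CPM, log2 3.47. The DLX family was 3 of 5 higher (3 adjusted over the list alone), Dlx1 at 115 ± 13.7 CPM against 32.8 CPM, log2 2.24, and calcium-binding proteins were 2 higher and 1 lower of 5 (3 and 1 adjusted over the list alone). In all, 716 genes were higher and 266 lower (1111 and 166 with voom). Voom ended the calls of Vip, Crh (also lost with a pseudocount of 0.1), Syt2 and Pvalb, and leaving out MouseID-410195 ended those of Penk, Vip (log2 7.86), Tac2 (5.77), Crh (5.31) and Pvalb (-3.10), MouseID-406074 also those of Tac2 and Crh, and MouseID-408805 those of Crh and Pvalb. The Sst-like share did not pass without MouseID-406074 (39.1 points above the other mice) or MouseID-408805 (34.9 points), nor the Vip-like share without MouseID-406074 (19 points) or MouseID-410195 (16.1 points).

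eHGT_064h labelled Sst-like and Pvalb-like cells, the Sst-like ones in the larger part. Sst-like cells made up 55.6% ± 4.06 against 18.2% in the other mice (n = 4, adjusted exact permutation p = 0.0163), and Pvalb-like cells 43.8% ± 5.12. Sst was at 6771 ± 1242 CPM against 1646 CPM, log2 difference 4.55, SE 1.28, adjusted p = 0.0299, Pdyn at 587 ± 217 CPM against 194 CPM, log2 4.24, Spp1 (chromosome 5, 104435111 to 104441053), which encodes osteopontin, at 29.4 ± 38.9 CPM against 1.01 CPM, log2 3.10, and the heparanase gene Hpse (chromosome 5, 100679484 to 100719716) at 21.9 ± 7.12 CPM against 7.42 CPM, log2 2.65. Spp1 ranged from 0.543 to 86.8 CPM over its 4 mice. Adarb2 fell to 0.142 ± 0.124 CPM against 215 CPM, log2 difference -4.44, SE 0.77, adjusted p = 7.20e-04, and the membrane glycoprotein gene Lamp5 (chromosome 2, 136052025 to 136069917) to 2.81 ± 2.40 CPM against 391 CPM, log2 -4.22. Sst markers were 6 of 8 higher (7 adjusted over the list alone), Elfn1 at 48.6 ± 14.8 CPM against 19.7 CPM, log2 2.14, and MGE markers 2 of 4 higher (4 adjusted over the list alone), Sox6 at 144 ± 25.5 CPM against 82.2 CPM, log2 1.57. CGE markers were 3 of 4 lower (3 adjusted over the list alone), Lamp5 markers 4 of 7 lower (4 adjusted over the list alone) and glutamatergic markers 5 of 7 lower (6 adjusted over the list alone). Neuropeptides were 4 higher and 1 lower of 16 (4 and 1 adjusted over the list alone). Interferon response genes were 2 of 10 higher (3 adjusted over the list alone), Ifit3 at 44 ± 9.32 CPM against 17.4 CPM. Calls were 128 higher and 348 lower, but 318 and 133 with voom and 311 in all without MouseID-497550. Leaving out any 1 of the 4 mice ended the call of Sst (log2 4.45 to 4.67), as did a pseudocount of 0.1 and the prefix letter as a covariate. Voom ended the calls of Adarb2 and Lamp5, the former also lost without the 3 enhancers of fewest genes per cell and the latter with a pseudocount of 0.1 or without MouseID-497550 (log2 -3.80). The Sst-like share did not pass without MouseID-468100 (35.5 points above the other mice), with letter G mice only, or with clusters named by fold against all cells.

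eHGT_140h labelled Pvalb-like cells. These made up 96.9% ± 3.57 of its cells against 34.9% in the other mice (n = 3, adjusted exact permutation p = 0.00363). Pvalb was at 2313 ± 42.9 CPM against 973 CPM, log2 difference 3.32, SE 1.06, adjusted p = 0.0426, the peptide Cartpt (chromosome 13, 99898483 to 99910179) at 179 ± 22.8 CPM against 45.9 CPM, log2 3.23, the sarcomere-linked genes Pdlim3 (chromosome 8, 45885487 to 45919635) at 76.6 ± 19.8 CPM against 18.2 CPM, log2 3.09 and Mybpc1 (chromosome 10, 88518279 to 88605229) at 90.8 ± 6.40 CPM against 33.9 CPM, log2 2.83. Sst fell to 119.6 ± 206 CPM against 2311 CPM, log2 difference -5.82, SE 1.45, adjusted p = 0.00936, and Dkk3 (chromosome 7, 112116019 to 112159482), a Dickkopf family gene, to 0.352 ± 0.501 CPM against 45.4 CPM, log2 -4.03. Pvalb markers were 3 of 7 higher (3 adjusted over the list alone). Fast-spiking channel genes were 5 of 12 higher (5 adjusted over the list alone), the channel subunit genes Kcnip2 at 295 ± 31.6 CPM against 112 CPM, log2 1.87 and Kcnc1 at 643 ± 168 CPM against 339 CPM, log2 1.35. Perineuronal net genes were 3 of 9 higher (3 adjusted over the list alone), Lamp5 markers 6 of 7 lower (7 adjusted over the list alone) and immediate early genes 4 of 12 lower (4 adjusted over the list alone). Glutamatergic markers were 7 of 7 lower (7 adjusted over the list alone), and Sst markers 4 of 8 lower (5 adjusted over the list alone). Calls came to 272 higher and 751 lower (455 and 370 with voom). Leaving out 1 of its own mice (any of 3) or 1 of 10 other mice ended the call of Pvalb (log2 3.28 to 3.33), and leaving out MouseID-460763 or MouseID-505190 ended those of Pdlim3 (2.94 to 3.02), Mybpc1 (2.79 to 2.82) and Sst (-4.80 to -4.24), the last also lost with voom. A pseudocount of 0.1 ended the calls of Pvalb and Pdlim3, and that of Pvalb also ended without a filter and without the 3 enhancers of fewest genes per cell.

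eHGT_128h labelled Pvalb-like cells with a minority Sst-like. Pvalb-like cells were at 85.6% ± 4.17 against 36% in the other mice (n = 3), which did not pass (adjusted exact permutation p = 0.0968), and Sst-like cells were at 14.4% ± 4.17. Pvalb was at 2274 ± 164 CPM against 977 CPM, log2 difference 3.29, SE 1.06, adjusted p = 0.0480, Mybpc1 at 83.8 ± 16.4 CPM against 34.6 CPM, log2 2.69, Syt2 at 104 ± 30.7 CPM against 52.4 CPM, log2 2.40 and the transmembrane glycoprotein gene Gpnmb (chromosome 6, 49036518 to 49058182) at 28.1 ± 7.43 CPM against 10.1 CPM, log2 2.33. Fxyd6 (chromosome 9, 45369470 to 45396159), a regulator of the sodium pump, was listed at 0 in all 3 mice against 219.9 CPM, and Lamp5 was at 0.0404 ± 0.0422 CPM against 391 CPM, log2 difference -6.01, SE 1.12, adjusted p = 0.00113. Fast-spiking channel genes were 7 of 12 higher (7 adjusted over the list alone), Kcnc1 at 599 ± 7.66 CPM against 344 CPM, log2 1.27 and Kcns3 at 169.9 ± 12.3 CPM against 92.3 CPM, log2 1.23. Perineuronal net genes were 3 higher and 1 lower of 9 (3 and 1 adjusted over the list alone), the net's core protein Acan at 9.87 ± 0.95 CPM against 3.79 CPM, log2 1.84. Glutamatergic markers were 7 of 7 lower (7 adjusted over the list alone), Lamp5 markers 6 of 7 lower (6 adjusted over the list alone) and Pvalb markers 3 of 7 higher (3 adjusted over the list alone). Calls were 182 higher and 715 lower (427 and 367 with voom), in all 556 without MouseID-475243 and 584 without MouseID-473546. Leaving out 1 of 22 mice, its own 3 among them, ended the call of Pvalb (log2 3.19 to 3.33), and leaving out any of its own 3 ended those of Mybpc1 (2.54 to 2.79) and Syt2 (2.25 to 2.67, also without 1 other mouse), while voom ended those of Fxyd6 and Lamp5. The calls of Pvalb, Mybpc1 and Syt2 also ended with a pseudocount of 0.1 and without the 3 enhancers of fewest genes per cell, and those of Pvalb and Syt2 without a filter and with the prefix letter as a covariate.

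eHGT_082h, with 2 mice, also labelled mainly Pvalb-like cells, at 83.2% ± 11.7 (n = 2), a share that did not pass (adjusted exact permutation p = 0.323). Adamtsl5 (chromosome 10, 80339793 to 80349030) was at 54.0 ± 14.6 CPM against 17.1 CPM, log2 difference 2.73, SE 0.63, adjusted p = 0.0163, the potassium channel modifier Kcng4 (chromosome 8, 119623854 to 119635680) at 22.7 ± 6.95 CPM against 5.46 CPM, log2 2.61, the sodium channel subunit Scn4b (chromosome 9, 45138624 to 45154155) at 30.1 ± 8.18 CPM against 7.13 CPM, log2 2.60 and Lrrc38 (chromosome 4, 143347076 to 143371032), a subunit of calcium-activated potassium channels, at 93.4 ± 1.61 CPM against 39.2 CPM, log2 2.39. Cplx3 fell to 0.0843 ± 0.119 CPM against 107 CPM, log2 difference -3.67, SE 1.01, adjusted p = 0.0441 and Tnnt1 to 0.0183 ± 0.0259 CPM against 29.2 CPM, log2 -2.60. Fast-spiking channel genes were 6 of 12 higher (6 adjusted over the list alone), Kcna1 at 418 ± 45.9 CPM against 181 CPM, log2 1.49. Perineuronal net genes were 3 of 9 higher (4 adjusted over the list alone), Pvalb markers 1 higher and 0 lower of 7 (3 and 1 adjusted over the list alone) and Lamp5 markers 4 of 7 lower (5 adjusted over the list alone). Calls were 176 higher and 141 lower (471 and 44 with voom), in all 209 without a filter, 108 without the 3 enhancers of fewest genes per cell, 114 without MouseID-473545 and 2 without MouseID-475242. Leaving out either mouse ended the calls of all 6 named genes, with log2 2.46 to 3.01 for Adamtsl5, 2.31 to 2.91 for Kcng4, 2.33 to 2.88 for Scn4b, 2.37 to 2.41 for Lrrc38, -3.79 to -3.56 for Cplx3 (also ended without 1 of 13 other mice) and -2.63 to -2.55 for Tnnt1 (18 other mice). The 6 calls also ended without the 3 enhancers of fewest genes per cell, and that of Kcna1 ended without MouseID-475242. Those of Cplx3 and Tnnt1 ended without a filter, with the prefix letter as a covariate and with voom too. A pseudocount of 10 ended that of Tnnt1, and a pseudocount of 0.1 those of Adamtsl5 and Lrrc38.

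eHGT_079h labelled Pvalb-like and Sst-like cells, at 68.1% ± 11.1 and 26.9% ± 7.19 (n = 3), and neither share passed (adjusted exact permutation p = 0.653 for Pvalb-like cells). Hpse was at 23.8 ± 14 CPM against 7.23 CPM, log2 difference 2.57, SE 0.41, adjusted p = 0.00131, the interferon-induced gene Ifit1 (chromosome 19, 34640889 to 34650009) at 21 ± 10.1 CPM against 7.53 CPM, log2 2.24, Lrrc38 at 79.2 ± 9.10 CPM against 40.6 CPM, log2 2.12 and Nog (chromosome 11, 89300638 to 89302559), the antagonist noggin of bone morphogenetic proteins, at 83.9 ± 23.4 CPM against 36.8 CPM, log2 1.96. Itpka fell to 1.45 ± 2.52 CPM against 79.8 CPM, log2 difference -3.11, SE 0.50, adjusted p = 0.00137, and the cortexin gene Ctxn1 (chromosome 8, 4257646 to 4259274) to 5.09 ± 3.26 CPM against 119 CPM, log2 -2.93. Fast-spiking channel genes were 3 of 12 higher (3 adjusted over the list alone) and interferon response genes 2 of 10 higher (2 adjusted over the list alone). Pvalb markers were 1 of 7 higher (4 adjusted over the list alone), glutamatergic markers 2 of 7 lower (7 adjusted over the list alone) and Lamp5 markers 2 of 7 lower (3 adjusted over the list alone). Id2, an inhibitor of DNA binding common in Lamp5 cells, was at 19.1 ± 13.9 CPM against 323 CPM, log2 -2.52. Calls were 82 higher and 271 lower, but 334 and 97 with voom, and in all 204 without a filter, 8 without MouseID-473544 and 137 without MouseID-505189. Leaving out MouseID-473544 ended the calls of Id2, Ifit1 (log2 2.44), Itpka (-2.71), Lrrc38 (2.03 to 2.17, also without either other mouse) and Nog (1.74 to 2.07, also without MouseID-505189). The calls of Ifit1, Lrrc38 and Itpka also ended with a pseudocount of 10, a pseudocount of 0.1 and voom, in that order.

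**Figure D2:**
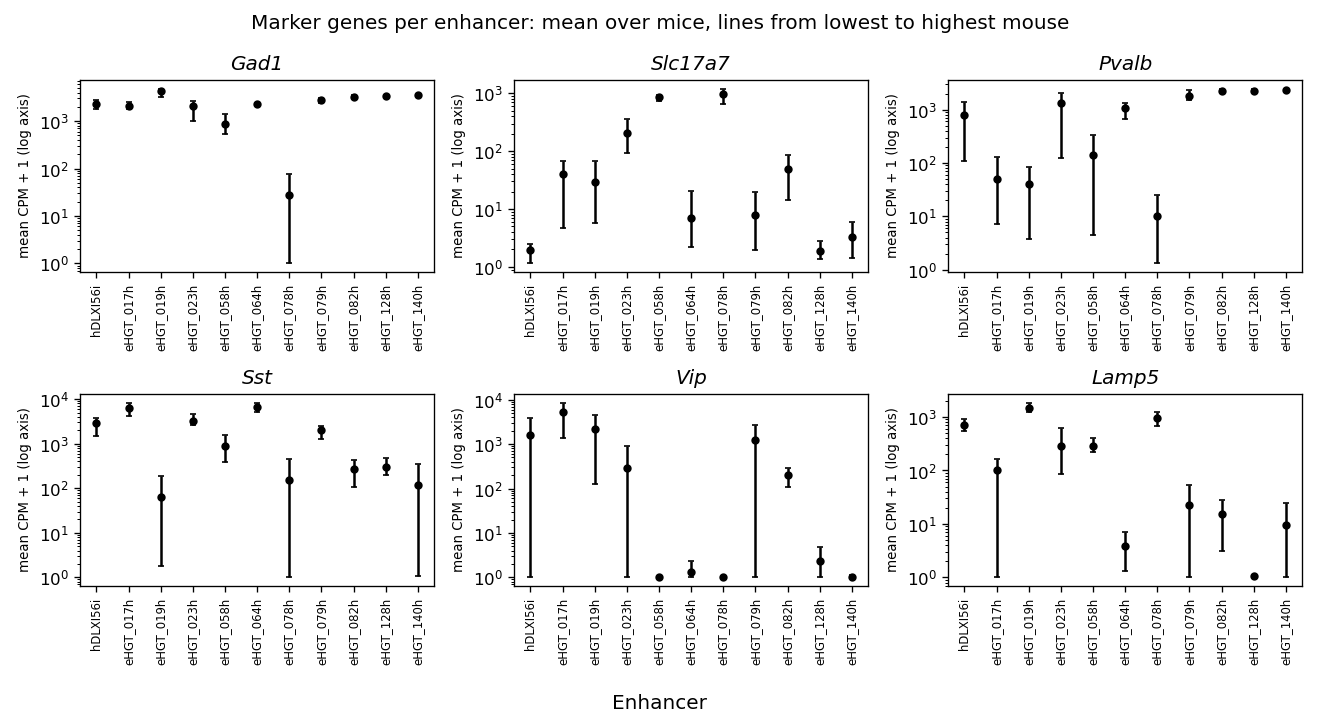
Expression of Gad1, Slc17a7, Pvalb, Sst, Vip and Lamp5 in 6 panels, as CPM + 1 on a log axis (y) for the 11 enhancers (x). Points are means over the mice of an enhancer and lines run from the lowest to the highest mouse; Slc17a7 is highest in eHGT_078h, at 978 CPM, where Gad1 is lowest, at 26.3 CPM.

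Whether Pvalb-like cells differ by the enhancer that labelled them was asked over 7 enhancers, 20 mice and 604 cells. There, 237 of 16475 genes differed in limma's omnibus test, and the Pvalb-like cells of hDLXI56i stood apart: 158 of the genes were lowest and 76 highest in them. Rpa1, a replication protein subunit, was at 5.81 ± 2.24 CPM (SD, n = 3) in hDLXI56i and 34.3 to 48.7 CPM in the other 6 enhancers (adjusted p = 1.17e-06). Chn1, Impa1, Cab39l and Osbpl1a were lowest there too, and Tcn2 was listed at 0. Pcdh19, a protocadherin, was highest there at 80.5 CPM, as were Bex1 at 216 CPM, against 40.5 CPM in eHGT_023h, and Mmd2 at 41.8 CPM. Members of the fixed lists that differed included Id2, Tac1 and Cartpt, highest in hDLXI56i, and Gad1, Pnoc, Hapln1, Hapln4, Kcna1, Kcnab1, Syt2 and Eno2, lowest in it. Of hDLXI56i's 46 Pvalb-like cells, 36 lay in 1 cluster, which held 0 cells of eHGT_023h and eHGT_082h, 1 of eHGT_128h, 3 of eHGT_064h, 8 of eHGT_079h and 13 of eHGT_140h, so the comparison sets cells of unlike clusters against each other. Without the 3 enhancers of fewest genes per cell, of which hDLXI56i alone was in this comparison, limma called 0 genes between the other 6 enhancers. There, 1334 of 15911 genes were at an unadjusted p under 0.05. The count was 1374 without MouseID-400157 or with at least 10 cells per mouse in place of 5, 102 without MouseID-384912, 143 without MouseID-473545, 146 without MouseID-475242 and 150 without MouseID-475243. MouseID-400157, of hDLXI56i, gave 8 Pvalb-like cells, with Pvalb at 536 CPM against 1691 to 3377 CPM in the other mice compared.

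Within Sst-like cells, 6 enhancers, 19 mice and 309 cells were compared, and 401 of 17214 genes differed. Sst itself was at 13340 CPM in hDLXI56i and 1931 ± 410 CPM in eHGT_128h (adjusted p = 1.22e-06). Fxyd7, a regulator of the sodium pump, was at 78.9 ± 8.66 CPM in eHGT_017h and 3.93 ± 0.949 CPM in eHGT_128h. Hpse was highest in eHGT_079h at 83.0 ± 40.1 CPM and listed at 0 in eHGT_128h, as were Rsph9, Crhr2 (also listed at 0 in eHGT_079h), Ecel1 and the potassium channel gene Kcnc4, which were highest in hDLXI56i or eHGT_017h. Kcnmb4, a potassium channel subunit, was highest in hDLXI56i at 61.3 CPM and lowest in eHGT_023h at 12.5 CPM. Atp2b4, a calcium pump, was at 29.2 CPM in eHGT_017h and 0.0847 CPM in eHGT_128h. Rnd2 was highest in eHGT_128h at 286 ± 10.4 CPM. Sst-like cells of eHGT_128h had the highest Pvalb, at 947 ± 103 CPM against 32.1 ± 28 CPM in eHGT_017h (adjusted p = 0.0412), and the highest Kcna1, Kcnc1 and Scn8a among fast-spiking channel genes. Reln, which encodes reelin, was highest in eHGT_017h at 443 CPM and lowest in eHGT_128h at 70.9 CPM. In 1 of the 4 Sst-like clusters lay 18 of 21 Sst-like cells of eHGT_128h, 27 of 38 of eHGT_079h and 25 of 70 of eHGT_017h. That cluster was left unnamed with the fold against all other cells, and the comparison was not run under that naming. Without the 3 enhancers of fewest genes per cell 174 genes passed, with the prefix letter as a covariate 215 and without a filter on low values 176. The count was 1505 without MouseID-400157, 255 without MouseID-406074, 236 without MouseID-408805 and 232 without MouseID-410195.

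Library names begin with SM-G or SM-J, a mark whose meaning is not given in the sources used here. Within the 5 enhancers that had both, 16 genes were higher and 3 lower in the 6 J mice than in the 10 G mice, of 17391 tested. With 1 mouse left out the higher ones numbered 12 to 16 and the lower ones 2 to 9, with 9 without MouseID-497551, 5 without MouseID-458159 or MouseID-492045, and 2 without MouseID-498749, MouseID-498750 or MouseID-505190 (2 also without a filter). Bc1, a brain cytoplasmic RNA, was at 77.3 CPM in J and 6.65 CPM in G mice (log2 difference 3.53, adjusted p = 7.19e-07). Dach2, a transcription factor, was at 9.95 and 33.9 CPM (log2 difference -1.65, adjusted p = 0.000339).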

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

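No test in this part was chosen after its result was seen. Values per mouse were searched for a mouse far from the others of its group by Dixon's test, which applies to groups of at least 4 and so only to eHGT_064h. In its 15 tested values, which were shares and the median reads and genes per cell, 5 of MouseID-468100 stood apart. Shares at 0 in all 4 mice were counted among the 15 and could not be marked. By transmitter genes, 2.13% of its cells were glutamatergic, against 0 in the other 3 mice. By clusters it had 97.9% GABAergic cells against 100% in the others, 2.13% L4 and L5 IT-like cells against 0, 36.2% Pvalb-like cells against 45.8% to 46.8%, and 61.7% Sst-like cells against 53.2% to 54.2%. A single glutamatergic cell accounts for 3 of the 5 values. Chance marks about 1 in 20 of such values, and 15 that depend on one another were tested, so more than 1 in 20 groups would be marked. A share at 0 in 3 mice stands apart by this test through a single cell. No explanation was tested.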

How the results depend on the processing

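The tests by limma voom, by other cluster names and without the 3 enhancers of fewest genes per cell (hDLXI56i, eHGT_017h and eHGT_019h) were chosen after the data were seen. edgeR with its size factor alternative and DESeq2, planned for a table of raw counts, were not run, on the recovered reads either. No mouse belongs to 2 enhancers, so mice were not paired, and prefixes shared by mice of different enhancers were not used as blocks. Where 1 eHGT_082h mouse was left out, the other was assumed to vary like mice of the other groups. Depth limits the shallowest cell, where 1 read is 1200.5 CPM, more than the median cell, where it is 1.71 CPM. Only cells with at least 4000 genes, both other Leiden resolutions, 1500 variable genes, thinning to 100000 reads, a threshold of 1 CPM, Pearson correlation, the 3000 most variable genes, pairs without a shared prefix and, for the counts of genes, a pseudocount of 0.1 changed no answer to a comparison. Over all left-out mice such answers were the same 5135 times, 14 passed newly or were counts that rose by over 1.5 times, and 54 no longer passed or were counts that fell by as much. Calls of single genes, and other values tested beside them, held 16670 times and were lost 907 times. They held and were lost 373 and 148 times with voom, 350 and 171 with a pseudocount of 10, 439 and 82 with 0.1, and 459 and 82 without a filter, while 40 were lost with the prefix letter. Without the 3 enhancers 276 held, 104 were lost and 1 reversed. The cause of the changes below was not tested, apart from the following. By construction, fewer mice enter where mice or enhancers were left out, and more genes are tested without the filter (36201 in place of 18932). The median SE in eHGT_023h widened with the prefix letter, from 0.35 to 0.434. Other cluster names do not enter the GABAergic share, where only the adjustment changed.

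With a pseudocount of 10 the counts of called genes were 132 in hDLXI56i, 293 in eHGT_017h, 611 in eHGT_019h, 28 in eHGT_023h, 880 in eHGT_058h, 126 in eHGT_064h, 992 in eHGT_078h, 97 in eHGT_079h, 113 in eHGT_082h, 281 in eHGT_128h and 301 in eHGT_140h. Voom gave 1042 in hDLXI56i, 435 in eHGT_023h and 515 in eHGT_082h. The prefix letter as a covariate gave 29 in eHGT_023h and 215 within the Sst class. Without a filter on low values the counts were 204 in eHGT_079h, 209 in eHGT_082h and 176 within the Sst class. Without the 3 enhancers of fewest genes per cell they were 108 in eHGT_082h, 0 within the Pvalb class (limma, 1334 genes at an unadjusted p under 0.05) and 174 within the Sst class, and Ndnf in eHGT_064h reversed to a log2 difference of 0.20. With at least 10 cells per mouse the Pvalb class had 1374. Leaving out 1 mouse gave 348 to 929 in hDLXI56i (lowest without MouseID-384912, highest without MouseID-400157), 36 to 155 in eHGT_023h (MouseID-497548), 311 to 502 in eHGT_064h (MouseID-497550), 8 to 421 in eHGT_079h (MouseID-473544), 2 to 354 in eHGT_082h (MouseID-475242) and 556 to 934 in eHGT_128h (MouseID-475243). It gave 102 to 1374 within the Pvalb class (MouseID-384912 and MouseID-400157) and 232 to 1505 within the Sst class (MouseID-410195 and MouseID-400157).

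Shares are differences from the other mice in percentage points. With clusters named by fold against all other cells, GABAergic cells in eHGT_058h (-63.8, adjusted exact p = 0.0526) and Sst-like cells in eHGT_064h (17.9) no longer passed, and by log2 difference neither did GABAergic cells in eHGT_058h (-63.8) and L2/3 IT-like cells in eHGT_078h (0). The GABAergic share was the same under all names, and only its adjustment over the other pairs changed. With letter G mice only, GABAergic cells in eHGT_058h (-64.6), Sst-like cells in eHGT_064h (40.3), and L2/3 IT-like (10.3) and unnamed glutamatergic cells (39.7) in eHGT_078h did not pass. At a threshold of 100 CPM, cells with both transmitters in eHGT_019h (1.31) did not. Leaving out 1 mouse ended the calls of GABAergic cells in eHGT_058h (29 mice, -69.2 to -61.1), Sst-like (MouseID-406074 and MouseID-408805, 34.9 to 51.9) and Vip-like cells in eHGT_017h (MouseID-406074 and MouseID-410195, 16.1 to 24.7), Sst-like cells in eHGT_064h (MouseID-468100, 35.5 to 39.5), and L2/3 IT-like (MouseID-453328 and MouseID-498749, 9.64 to 27) and unnamed glutamatergic cells in eHGT_078h (MouseID-453328 and MouseID-454782, 16.1 to 38.9). Unnamed glutamatergic cells in eHGT_058h passed without MouseID-454782 (20.4, with a range of 16.9 to 20.4 over all left-out mice). By transmitter genes, GABAergic and glutamatergic shares of eHGT_058h passed without MouseID-400156, MouseID-453328, MouseID-454782, MouseID-497548 or MouseID-498749. There the GABAergic difference was -61.4 to -59.4 and the glutamatergic one 62.9 to 66.2. Over all left-out mice these differences were -64.3 to -55.3 and 60.1 to 68.2.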

Other observations

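Of the tests in this part, the comparison of depth between hDLXI56i and the other mice, and the counts of Slc17a7 by cluster, were chosen only after the results were seen. Lists not given with each enhancer are reported here as counts over all genes, with counts adjusted over the list alone in brackets where they differ. Enhancers with 0 called over all genes are left out. Calcium-binding proteins, 5 of them, were 1 higher in hDLXI56i (Necab2), 2 higher and 2 lower in eHGT_019h, 2 and 1 in eHGT_058h, 1 and 1 in eHGT_078h, 1 and 1 [1 and 3] in eHGT_128h, 1 and 3 in eHGT_140h, 1 and 0 [3 and 2] in eHGT_064h and 0 and 1 [1 and 2] in eHGT_079h. Calb1 was at 1969 ± 498 CPM against 778 CPM, log2 1.77 in eHGT_064h, and Necab2 at 196 ± 62.1 CPM against 26.6 CPM, log2 3.88 in eHGT_019h and 1.86 ± 1.67 CPM against 46.1 CPM, log2 -2.99 in eHGT_140h. Of 4 Sncg markers, eHGT_019h had 3 higher, eHGT_017h 2, eHGT_058h and eHGT_078h 1 [and 1 lower] and eHGT_082h 1, while 1 [2] was lower in eHGT_064h and eHGT_079h and 2 [3] in eHGT_128h. The cannabinoid receptor gene Cnr1 was at 651 ± 392 CPM against 120.2 CPM, log2 2.89 in eHGT_017h and 25.1 ± 1.93 CPM against 183 CPM, log2 -2.05 in eHGT_128h. Of 4 chandelier markers 2 [3] were higher in eHGT_017h, 1 in hDLXI56i, 1 in eHGT_064h and 1 in eHGT_078h, and 1 was lower in eHGT_058h, eHGT_078h, eHGT_082h, eHGT_128h and eHGT_140h [also 1 higher]. Cpne5 was at 82.9 ± 25.4 CPM against 20.9 CPM, log2 2.36 in eHGT_017h and 4.11 ± 3.01 CPM against 28.8 CPM, log2 -2.23 in eHGT_128h. Transmitter genes were 2 of 4 higher in eHGT_019h, 1 higher and 3 lower in eHGT_078h, 1 and 1 in hDLXI56i and eHGT_058h, 1 higher in eHGT_023h, and 1 lower in eHGT_064h, eHGT_128h and eHGT_140h [the last 2 also 1 higher]. Gad2 was at 2017 ± 247 CPM against 563 CPM, log2 2.57 in eHGT_019h and 1218 ± 72.4 CPM against 643 CPM, log2 1.77 in hDLXI56i.

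Other lists went as follows, each pair being genes higher and lower. Interferon response genes (10) were 2 and 0 in eHGT_017h, 1 and 0 [2 and 0] in eHGT_023h, 0 and 1 in eHGT_058h, 0 and 2 [0 and 3] in eHGT_078h and 0 and 2 in eHGT_140h. Immediate early genes (12) were 0 and 1 in eHGT_017h, 0 and 2 in eHGT_019h and 0 and 2 [0 and 6] in eHGT_128h. Perineuronal net genes (9) were 1 and 2 in eHGT_017h, 1 and 2 in eHGT_058h, 0 and 1 in eHGT_064h, 1 and 3 in eHGT_078h and 2 and 0 in hDLXI56i. Neuropeptides (16) were 1 and 4 in eHGT_058h, 0 and 2 in eHGT_128h and 1 and 4 [2 and 4] in eHGT_140h. Fast-spiking channel genes (12) were 0 and 2 in eHGT_017h and 1 and 0 in hDLXI56i. DLX family genes (5) were 3 and 0 in eHGT_019h. GABAergic markers (6) were 2 and 0 [3 and 0] in eHGT_017h, 5 and 0 in eHGT_019h and 1 and 0 in eHGT_140h. Glutamatergic markers (7) were 0 and 1 in eHGT_017h and 0 and 3 in eHGT_019h. MGE-derived markers (4) were 1 and 0 in eHGT_017h, 0 and 2 in eHGT_058h, 0 and 3 in eHGT_078h, 1 and 0 in eHGT_079h, 1 and 0 [2 and 0] in eHGT_128h and 1 and 0 in eHGT_140h. CGE-derived markers (4) were 0 and 4 in eHGT_078h, 0 and 2 [0 and 4] in eHGT_128h and 0 and 2 [0 and 3] in eHGT_140h. Pvalb markers (7) were 1 and 2 [2 and 2] in eHGT_017h, 0 and 3 [0 and 5] in eHGT_058h, 1 and 0 in eHGT_064h and 1 and 4 in eHGT_078h. Sst markers (8) were 2 and 3 in eHGT_019h, 1 and 0 [2 and 0] in eHGT_023h, 0 and 4 [0 and 5] in eHGT_078h, 1 and 0 in eHGT_079h, 0 and 2 in eHGT_128h and 1 and 0 in hDLXI56i. Vip markers (7) were 1 and 1 in eHGT_019h, 0 and 1 in eHGT_058h and 0 and 1 in eHGT_140h. Lamp5 markers (7) were 3 and 0 in eHGT_017h, 2 and 0 [3 and 0] in eHGT_058h and 2 and 2 in eHGT_078h. L2/3 IT markers (8) were 0 and 1 in eHGT_017h, 1 and 2 in eHGT_019h, 1 and 0 [2 and 0] in eHGT_023h, 1 and 0 [1 and 1] in eHGT_058h and 1 and 0 in eHGT_064h. L4 and L5 IT markers (8) were 2 and 1 in eHGT_019h, 0 and 2 [0 and 4] in eHGT_064h, 0 and 2 [0 and 3] in eHGT_128h, 0 and 3 [0 and 4] in eHGT_140h and 1 and 0 in hDLXI56i. L5 ET markers (6) were 2 and 0 [2 and 1] in eHGT_019h, 2 and 3 in eHGT_058h, 0 and 2 in eHGT_128h, 0 and 1 in eHGT_140h and 1 and 1 [1 and 2] in hDLXI56i. L6 CT markers (4) were 1 and 0 in eHGT_017h, 2 and 0 in eHGT_058h, 0 and 2 in eHGT_128h and 0 and 1 in hDLXI56i.

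Of 6 L6 IT markers 2 were higher in eHGT_017h and 2 in eHGT_078h, and 1 was higher and 1 [2] lower in eHGT_058h. Of 6 L5/6 NP markers 2 were higher and 1 lower in eHGT_058h, 1 and 1 in hDLXI56i and eHGT_078h, 1 higher in eHGT_017h and eHGT_019h, 1 lower in eHGT_064h [and 1 higher] and eHGT_128h, and 2 lower in eHGT_140h. Of 4 L6b markers 2 were higher in hDLXI56i and 1 in eHGT_058h [and 2 lower], 1 was higher and 1 lower in eHGT_019h, and 1 was lower in eHGT_017h, eHGT_064h [and 1 higher], eHGT_078h, eHGT_082h and eHGT_128h [and 1 higher]. Some genes stand on more than 1 list, so counts of different lists are not all separate. Among them are Cplx3 (L6b and Lamp5), Crym (L5 ET and L6 CT), Calb1 (L2/3 IT and calcium-binding), Penk (Vip, L6 IT and neuropeptides) and Vcan (OPC and perineuronal net). More than 50% of a list at 10 CPM or more was found in 1482 cells for neurons, 26 for astrocytes, 8 for oligodendrocytes, 3 for microglia, 1 each for endothelium, pericytes and VLMC, and 0 for OPC. Of 5 neuron markers Rbfox3 alone was called, higher in eHGT_019h (313 ± 114 CPM against 142 CPM, log2 1.31), eHGT_058h and eHGT_078h and lower in eHGT_128h (61.8 ± 4.63 CPM against 167 CPM, log2 -1.19) and eHGT_140h. Astrocyte markers went both ways. Of 6, eHGT_019h had 3 higher and 1 lower, eHGT_058h and eHGT_078h 2 and 1, eHGT_064h, eHGT_128h and eHGT_140h 2 lower, hDLXI56i 1 lower and eHGT_079h 1 [2] lower. In eHGT_058h Slc1a2, a glutamate transporter, was at 408 ± 127 CPM against 49.3 CPM, log2 3.93, Aldh1l1 at 41.3 ± 13 CPM against 3.28 CPM, log2 4.32 and Aldoc at 53.5 ± 26.4 CPM against 154 CPM, log2 -1.36. Endothelial markers were 3 of 3 higher in eHGT_078h, Ly6c1 at 7.25 ± 12.5 CPM against 0.0505 CPM, log2 1.49, but all 3 calls rest on MouseID-454782, which had Ly6c1 at 21.66 CPM. Without it Ly6c1 and Flt1 fall under the filter, and Pecam1 has a log2 difference of 0.65. The OPC list had 3 of 4 higher in eHGT_017h, 1 in eHGT_019h and 1 [2] in hDLXI56i, with 1 lower in eHGT_128h. Mbp of the oligodendrocyte list was at 125 ± 39.9 CPM against 49.2 CPM, log2 1.59 in eHGT_078h and was called in eHGT_058h too [0 over the list alone]. Dcn, the 1 VLMC gene tested, was higher in eHGT_017h and eHGT_064h. Microglia, pericyte and housekeeping genes had 0 called by limma in each enhancer.

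Counts of called genes were set against 100 splits of the mice into groups of the same sizes, the real one included, except for eHGT_082h with its 2 mice. Within the Pvalb class, 2 of the 7 enhancers also had 2 mice. As many genes as in the real split came from 1 split for eHGT_019h (1821, highest other 1670), eHGT_058h (2369, 1103), eHGT_064h (476, 18), eHGT_078h (2717, 1923), eHGT_128h (897, 324) and eHGT_140h (1023, 25). The same held for the Pvalb class (237, 67), the Sst class (401, 9) and the prefix letter (19, 0). It came from 3 splits for eHGT_017h (982, 1459), 3 for hDLXI56i (588, 2011), 4 for eHGT_079h (353, 1997) and 5 for eHGT_023h (123, 2091). Chance is excluded at 0.05 for the Pvalb class, the Sst class and the prefix letter. For single enhancers it is not excluded, since all enhancer labels were reassigned at once, which asks only whether any enhancer differs. Splits that call several times the real count, as for hDLXI56i, eHGT_079h and eHGT_023h, point to a structure of the samples, which was not examined further.

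The Pvalb-like cells of hDLXI56i stood apart from those of 6 other enhancers. Median reads per Pvalb-like cell were 0.958 of those of the other mice (578817 and 604481, exact permutation p = 0.558). This argues against fewer reads as the cause. Median genes per cell were still fewer (8748 and 9896, exact permutation p = 0.000877). Reads are not independent molecules here, so like reads leave open what the fewer genes reflect. Of the genes lowest in these cells, 157 had a value in Sst-like cells. Of those, 89.8% were also lower in the Sst-like cells of hDLXI56i (48.5% of all genes). A difference between animals or libraries of hDLXI56i that reaches its Sst-like cells too may thus be the cause. This count cannot tell it from an unlike mix of Sst-like clusters. The largest Sst-like cluster held 7 of 32 Sst-like cells of hDLXI56i and 25 of 70 of eHGT_017h. It held 54 of 103 of eHGT_064h, 32 of 45 of eHGT_023h, 27 of 38 of eHGT_079h and 18 of 21 of eHGT_128h. A technical difference common to hDLXI56i and eHGT_017h may be another cause. Of the 157 genes, 72.0% were lower in Sst-like cells of eHGT_017h (44% of all genes), to which the same limit applies. The 2 share no library prefix, and no label dates the libraries. Their mice and those of eHGT_019h run from MouseID-382159 to MouseID-410195, and all other mice from MouseID-453328 upward. Whether these numbers follow time is not given in the sources used here. Whether either difference reaches all cells of each mouse was not tested over these genes. For Rpa1 alone, MouseID-400157 of hDLXI56i had 4.41 CPM in Pvalb-like cells but 30.9 CPM in Sst-like cells. The Sst-like cells of MouseID-382159 and MouseID-384912 had 9.50 and 3.95 CPM. Lamp5-like cells of hDLXI56i had Rpa1 at 16.7 to 33.2 CPM, against 29.96 to 56.9 CPM in eHGT_019h. Which Pvalb-like cells hDLXI56i labels stays open too, untested, with most of its cells in a cluster that few cells of the others entered.

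Among the GABAergic cells of eHGT_019h with at least 4000 genes, 28 had Slc17a7 at 10 CPM or more and 99 did not, and the shares per mouse and per cluster had been seen before the tests were planned. RNA of glutamatergic cells, or doublets, may be the cause, since the 6 other glutamatergic markers rose with Slc17a7 by a median of 0.564 (0.216 for Neurod6 to 0.660 for Nrn1) of the rise expected from their ratio in glutamatergic cells, where Slc17a7 averaged 986 CPM against 108 CPM here. Lamp5-like cells with Slc17a7 were 19.9% ± 13.9 in eHGT_019h and 0 in hDLXI56i, a difference of 19.9 points (n = 3 and 3, exact permutation p = 0.1, the smallest this design can give and past no threshold). That comparison pools 3 clusters in unlike proportions, and within them 13 of 40, 4 of 25 and 3 of 43 cells of eHGT_019h had Slc17a7 and 0 of 10, 0 of 12 and 0 of 34 of hDLXI56i, which goes against the cluster mix as the whole cause, from few cells. Low expression of Slc17a7 in these cells themselves was not tested.

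The 3 mice of eHGT_023h all had prefix letter J. Of the 123 genes called for it, 58 (47.2%) differed in the same direction between the letters within the 5 enhancers that had both. Their median log2 difference between letters was -0.056. Most tested genes were not higher in J mice, so a share near this can arise without a letter effect. This argues only against a letter effect on these genes that those 5 enhancers share. Genes near 0 in several of them, such as Slc17a7, have little weight in this count. It cannot show an effect of the library set on the class mix of eHGT_023h alone. With the letter as a covariate 29 of the 123 passed. The median absolute log2 difference of the 123 was 1.73 before and 1.70 after, and the median SE 0.35 and 0.434, so the calls ended through the wider SE. The mix of classes in these mice, and chance, stay open.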
